A study of Mus musculus with 9 samples.

How the data were processed

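RNA from sorted mesenchymal cells of thymus, bone and truncal skin of C57BL/6 mice was sequenced in 9 libraries, 3 per tissue. Per the labels' protocols, thymus and bone were digested with enzymes, and at least 25000 cells negative for the lineage antibodies and positive for SCA1 were sorted per sample. The bone preparation also included crushing with a pestle and lysis of red cells, per the labels' protocols. The digestion of skin is not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, HTSeq 0.5.4 and the mouse build mm10, with no role for each. The aligner, the gene annotation and the strand setting are not given in the sources used here.

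The deposited count tables hold whole reads per gene symbol for 23420 genes, with 5 summary lines in the layout of HTSeq. The deposited RPKM tables give, per gene, its mm10 coordinates, an RPKM value made by the authors and a whole number. That whole number, the deposited signal, is the sum of read bases over the gene, since it came to a median of 98.5 to 99.1 times the read count, and it was used only to check the RPKM column. RPKM and signal differed by 1 factor per library and 1 per gene. Of the symbols with an RPKM value, 23034 had a single line, and 23015 of them were also in the count tables. Symbols with more lines were left out of the tests on RPKM. Coordinates are those of the deposited RPKM tables in mm10. No gene encoded by the mitochondrial genome was among those counted.

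Summary lines took 5.05 to 14.8% of the reads in the count tables and were left out of library sizes and tests. Reads on no gene made up 13.2 ± 0.825% in bone, 9.61 ± 0.478% in thymus and 4.88 ± 0.519% in skin (SD, n = 3). The 10 genes with most reads took 32.6% of gene reads in skin, 19.5% in bone and 14.3% in thymus. Replicate libraries were compared gene by gene with a chi-square statistic, which was 96.3 to 306.5 per degree of freedom, so no library looked like a copy of another and each was counted as 1 replicate. At this depth that statistic does not show that the libraries are separate samples. The replicate numbers do not pair samples across tissues by the labels, and the fit was made without a block.

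Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust estimation, after TMM scaling and filterByExpr by tissue, which left 15635 genes. All 9 libraries entered 1 fit with a mean per tissue, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. TMM factors were 1.104 to 1.179 in thymus, 1.161 to 1.233 in bone and 0.701 to 0.77 in skin, and the levels in CPM are scaled by library size and these factors. A gene was called apart in a tissue when it passed against both other tissues in the same direction by at least 2-fold. Overlaps were set beside 20 draws of simulated unchanged groups per tissue and beside the overlap of independent lists. A group with 0 reads was set to a floor of 3 reads over its 3 libraries, and with 1 to 3 reads the ratio is given with its 95% counting interval. The floors were 0.00881 CPM in thymus, 0.0096 in bone and 0.0123 in skin.

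The 34 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists cover mesenchymal identity, antibody targets, 10 sets of markers of other cell types, skeletal, adipogenic and dermal genes, niche factors and thymopoietic ligands. They also cover Hox paralogue groups and other positional factors, antigen presentation, interferon, inflammatory, stress and cell cycle genes, matrix genes, and Wnt, BMP and TGF-beta, and retinoic acid genes. Camera of limma 3.58.1 tested each list in each of the 3 comparisons with a preset correlation of 0.01 between genes, adjusted over 102 tests, and again with an estimated correlation. Per comparison, the named genes are the 6 largest and the 6 lowest log2 fold changes past the threshold with a mean of at least 20 CPM in the higher tissue and no overlap between the groups. Predicted genes named Gm or Rik, receptor and antibody segments, haemoglobins and small RNAs were left out of that ranking. Up to 3 members of each list with the smallest p were added, and for each tissue against both others the 8 higher and 4 lower genes with the largest smaller fold change. Ly6a and the antibody targets were always named, and a gene named by the rule in 1 comparison may be given in others. The genes of the closing tests, which belong to marker lists written before those tests, are named there outside this rule, and those singled out were chosen after their values were seen.

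The alternatives were RLE and upper quartile factors, library size only, no filter, a filter of 1 CPM or more in 3 libraries, DESeq2 1.42.0, and limma on log2 of RPKM plus 1 or plus 0.1 for genes with an RPKM of 1 or more in 3 libraries. Limma on log2 of RPKM plus 1 was also run without that filter. Fits with the replicate number as a block, with only the 2 tissues compared and with each library left out were also made. Fits without the genes on chromosomes X and Y were added after seeing the data. The steps were tested on simulated counts for thymus and bone over 15116 genes. Of 50 genes per class, 82% raised 4-fold and 84% lowered 4-fold were called, as were 40% raised 2-fold and 32% lowered 2-fold, with 4 calls among 14916 unchanged genes. All simulated libraries had the bone means apart from these few changed genes, whereas the real comparisons called 32.6 to 47.1% of genes. The simulation also held no shift in composition like that of skin. Its shares therefore do not carry over to the real comparisons. Tables were read with Python 3.11.15 and figures drawn with matplotlib 3.10.9.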

Results

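Gene expression was measured by RNA sequencing in mesenchymal cells sorted from 3 tissues of C57BL/6 mice aged 3 to 4 weeks. The tissues were the thymus, bone (pelvis, femur and tibia) and truncal skin (dermis of the back and abdomen), with 3 libraries each. The cells carried SCA1, a surface protein of many stromal and progenitor cells encoded by Ly6a, and were negative for antibodies against blood, endothelial and epithelial cells. The labels name the thymus libraries 2, 3 and 1-3 without saying what the last name means. If it is a pool of samples 1 to 3, it shares material with the other 2, and the thymus SD and p-values then rest on fewer than 3 separate samples. Gene reads per library ranged from 78757872 in bone to 116759235 in skin. Bone libraries held 13155 ± 110 genes at a read count of 1 CPM or more, thymus libraries 12506 ± 185 and skin libraries 11782 ± 191 (SD, n = 3). Libraries of 1 tissue correlated at r = 0.986 to 0.995 across genes on a log scale, and libraries of different tissues at r = 0.919 to 0.945, where genes are not independent replicates. Levels below are in CPM, the reads of a gene scaled by library size and TMM factor, as mean ± SD over n = 3 libraries. Values in brackets after a gene are log2 fold changes ± SE, the first tissue named in the comparison minus the second. The SE was worked back from the test, as the absolute log2 fold change over the square root of its F statistic. It is thus approximate and not the SE of a fitted coefficient. The labels do not say that the 3 libraries of a tissue came from separate animals, so p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

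Transcripts of the sort markers were measured first. Ly6a stood at 427 ± 49.7 CPM in thymus, 280.1 ± 43.8 in bone and 948 ± 380.1 in skin. It was lower in bone than in skin (-1.76 ± 0.25, adjusted p = 0.000146) and lower in thymus than in skin (-1.15 ± 0.24, adjusted p = 0.00306), the latter call being lost with library size only and on RPKM. Ptprc, which encodes CD45 of blood leukocytes, was at 76.4 ± 4.21 in bone, 20 ± 16.5 in thymus and 1.29 ± 0.905 in skin, and the means were 10.7 in thymus without thymus 3 and 0.807 in skin without skin 1. Itgam, encoding CD11b of myeloid cells, was at 73.1 ± 8.48 in bone, 1.06 ± 0.453 in thymus and 3.79 ± 1.52 in skin. Cd4 was at 18.2 ± 8.92 in thymus, and Itga2b, which encodes CD41 of platelets and their precursors, at 18.8 ± 6.48 in bone and 17.7 ± 2.46 in skin. Pecam1, the CD31 gene, was at 10.8 ± 2.71, 13.9 ± 1.23 and 6 ± 1.82 in thymus, bone and skin. Epcam, an epithelial adhesion gene, was at 1.25 ± 0.413, 0.16 ± 0.189 and 3.31 ± 1.73 in the same order. Cd2 was at 3.77 ± 2.17 in thymus and 3.11 ± 1.11 in bone. Of 8 antibody targets tested, 6 were higher and 1 lower in bone than in skin, the same adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.315 with an estimated correlation). Between thymus and skin 4 were higher and 2 lower in thymus, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.67).

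Thymus was compared with bone to describe how the mesenchymal cells of these organs differ. The thymus cells carried more of Col6a4, a collagen VI chain, at 576 ± 77.5 CPM against 2.07 ± 0.873 (8.12 ± 0.41, adjusted p = 4.17e-07). Ltc4s, the synthase of cysteinyl leukotrienes, was at 117 ± 27.8 against 0.226 ± 0.219 (8.95 ± 0.80). Atcay was 4860-fold (95% counting interval 1350 to 40200) higher in thymus and Mrgprg, a Mas-related receptor gene, 5830-fold (95% counting interval 1610 to 48100) higher. Bone cells carried Prg4, the joint lubricant lubricin, at 38500 ± 9156 against 16 ± 4.58 (-11.24 ± 0.59, adjusted p = 7.07e-07), and Col10a1, the collagen of hypertrophic cartilage, at 574 ± 269 against 0.13 ± 0.0892 (-12.05 ± 0.63). Ibsp, encoding bone sialoprotein, and Clec3a, a cartilage lectin gene, were also lower in thymus (-11.88 ± 1.00 and -11.84 ± 0.61). Extl1 and Ablim3 were higher in thymus (9.76 ± 0.77 and 7.70 ± 0.77). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2584 genes were higher and 2517 lower in thymus of 15635 tested, 1382 and 1724 of them by at least 2-fold. In mm10, Col6a4 lies on chromosome 9, 105990318 to 106096691, Prg4 on chromosome 1, 150449412 to 150466165, Col10a1 on chromosome 10, 34389981 to 34397085 and Ibsp on chromosome 5, 104299287 to 104311472.

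Cartilage and bone genes were lower in thymus. Of 17 chondrogenic genes, 16 were lower, and 17 adjusted over the list alone (camera adjusted p = 6.5e-26, adjusted p = 0.00268 with an estimated correlation). Acan, encoding the cartilage proteoglycan aggrecan, was at 175 ± 37.3 in bone and 0.0503 ± 0.0145 in thymus (-11.74 ± 0.35). Comp, a cartilage matrix gene, was at 1102 ± 84.6 and 1.93 ± 0.584 (-9.16 ± 0.46). Osteogenic genes were lower for 10 of 15, also 10 adjusted over the list alone (camera adjusted p = 7.38e-08, adjusted p = 0.0418 with an estimated correlation). Spp1, encoding osteopontin, was at 454 ± 194 in bone and 0.483 ± 0.367 in thymus, and Sp7, the osteoblast transcription factor osterix, was 2980-fold (95% counting interval 534 to 118000) lower in thymus. Small leucine-rich proteoglycans had 4 members higher and 4 lower of 12, the same adjusted over the list alone (camera adjusted p = 0.0172, adjusted p = 0.395 with an estimated correlation). Kera and Fmod, genes of keratocan and fibromodulin, were lower (-6.06 ± 0.29 and -6.01 ± 0.32). Collagen and fibre genes had 14 of 29 higher and 7 lower, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.092, adjusted p = 0.696 with an estimated correlation). Col15a1, a collagen of basement membrane zones, was at 6841 ± 1122 in thymus against 652 ± 83.2 (3.39 ± 0.21). Fn1, encoding fibronectin, was at 2411 ± 721 against 36950 ± 4514 (-3.94 ± 0.27), while Postn, encoding periostin, was higher (2.59 ± 0.22).

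Hox genes, which pattern the body axis, divided by paralogue group. Hoxa10 had 0 reads in the thymus libraries and 36.6 ± 11.2 CPM in bone, at least 4160-fold lower in thymus with a floor of 3 reads over the group. Hoxa11 was at least 2600-fold lower on the same floor. Of 13 genes of groups 9 to 13, 11 were lower in thymus, and 12 adjusted over the list alone (camera adjusted p = 2.79e-20, adjusted p = 0.00268 with an estimated correlation). Groups 1 to 4 went the other way, with 8 of 10 higher in thymus and 8 adjusted over the list alone (camera adjusted p = 2.47e-05, adjusted p = 0.201 with an estimated correlation). Hoxb2 was at 17.1 ± 4.12 against 1.05 ± 0.326 (4.02 ± 0.28), and Hoxb3 and Hoxd3 were also higher (3.71 ± 0.34 and 3.48 ± 0.43). Groups 5 to 8 had 1 higher and 4 lower of 11, or 1 and 5 adjusted over the list alone, and did not pass (adjusted p = 0.115). Limb field factors were lower for 6 and higher for 3 of 12, the same adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.209 with an estimated correlation). Pitx1, a hindlimb factor, was 3450-fold (95% counting interval 955 to 28500) lower in thymus, and Tbx4, another hindlimb factor, was lower (-4.62 ± 0.47). Pharyngeal and neural crest factors had 7 higher and 6 lower of 21, or 7 and 7 adjusted over the list alone, and did not pass (adjusted p = 0.819). Meox1, a homeobox gene, was at 214 ± 40 in thymus and 15.7 ± 2.91 in bone (3.77 ± 0.21), and Hand2 was higher (2.61 ± 0.26). In mm10, Hoxa10 lies on chromosome 6, 52231197 to 52240854 and Hoxa11 on chromosome 6, 52242106 to 52245242. Hox clusters hold overlapping and antisense genes and the strand setting of the counts is not given in the sources used here, so single Hox values are uncertain to that extent.

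**Figure D1:**
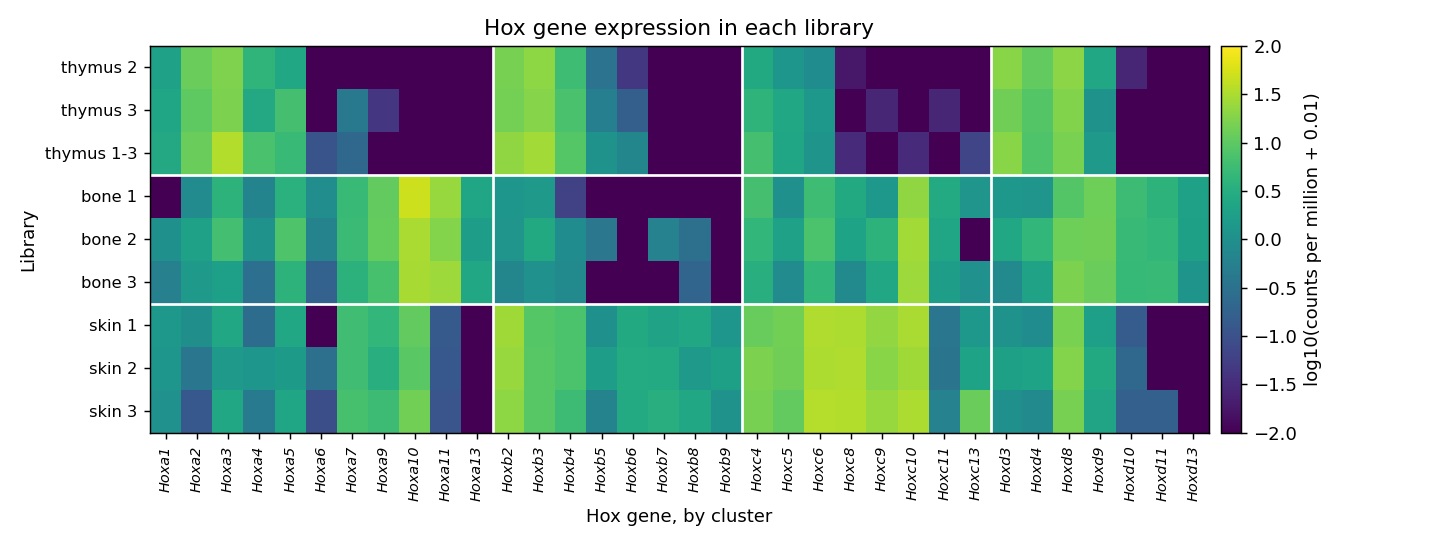
Hox genes (columns, by cluster) in each of the 9 libraries (rows), as log10 of normalised read counts in CPM plus 0.01, with the low end of the colour scale at 0 reads. Hoxa10 and Hoxa11 had 0 reads in the 3 thymus libraries, and Hoxb2 was at 17.1 in thymus, 23.8 in skin and 1.05 in bone.

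Genes that act on blood and thymus cells also differed. Ccl19, a chemokine that draws CCR7-bearing cells, was at 60.8 ± 4.37 in thymus against 4.09 ± 0.567 in bone (3.90 ± 0.19). Flt3l, a growth factor of early lymphoid and dendritic cells, was at 110.5 ± 31.1 against 8.64 ± 1.27 (3.68 ± 0.26). Thymopoietic ligands were higher in thymus for 8 and lower for 2 of 15, the same adjusted over the list alone (camera adjusted p = 0.000468, adjusted p = 0.162 with an estimated correlation). Cxcl12, a chemokine that holds blood progenitors in marrow, was at 231 ± 34.8 in thymus and 962 ± 117 in bone (-2.06 ± 0.19). Lepr, the leptin receptor gene, and Foxc1, a forkhead factor gene, were lower in thymus too (-2.33 ± 0.19 and -2.25 ± 0.14). Haematopoietic niche factors had 5 lower and 2 higher of 12, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.285 with an estimated correlation). MHC class I processing genes were higher in thymus for 16 of 18, also 16 adjusted over the list alone (camera adjusted p = 8.17e-10, adjusted p = 0.154 with an estimated correlation). H2-K1 was at 1038 ± 65 against 155 ± 13.9, and Psmb10 and Tap2, of the immunoproteasome and the peptide transporter, were higher (1.98 ± 0.20 and 1.82 ± 0.21). Reads of H2 genes may be shared among near-identical family members. Interferon response genes were higher for 12 and lower for 1 of 20, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.000766, adjusted p = 0.574 with an estimated correlation), with Irf1 lower (-1.15 ± 0.18). MHC class II genes did not pass (adjusted p = 0.334).

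Immediate early and dissociation stress genes were lower in thymus for 13 and higher for 3 of 18, or 14 and 3 adjusted over the list alone (camera adjusted p = 2.5e-08, adjusted p = 0.188 with an estimated correlation). Nr4a1, an early response receptor gene, was at 63.2 ± 21.6 in thymus and 974 ± 76.3 in bone (-3.95 ± 0.24), and Ier3 and Klf4 were lower (-2.77 ± 0.25 and -2.25 ± 0.22). Cell cycle genes were lower for 9 of 20, and 14 adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.594 with an estimated correlation), with Rrm2 and Pcna among them (-2.23 ± 0.34 and -0.91 ± 0.18). Inflammatory genes had 3 higher and 6 lower of 17, or 3 and 7 adjusted over the list alone, and did not pass (adjusted p = 0.69). The eosinophil chemokine gene Ccl11 was higher in thymus (6.66 ± 0.33) and the neutrophil chemokine gene Cxcl2 lower (-6.04 ± 0.63). Mesenchymal identity genes had 6 higher and 5 lower of 16, or 7 and 5 adjusted over the list alone, and did not pass (adjusted p = 0.819). Among them Eng, encoding endoglin, was higher in thymus (2.71 ± 0.18) and Nt5e, encoding the ecto-nucleotidase CD73, lower (-5.71 ± 0.40). Dermal fibroblast genes had 3 higher and 2 lower of 11, the same adjusted over the list alone, and did not pass (adjusted p = 0.517), with Tbx15 at 4.38 ± 0.535 in thymus and 144 ± 8.89 in bone (-5.04 ± 0.17).

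Markers of other cell types moved with the tissue in this comparison. In bone, 14 of 16 myeloid markers were above thymus, and 15 adjusted over the list alone (camera adjusted p = 7.18e-30, adjusted p = 0.0349 with an estimated correlation). The neutrophil granule gene Ngp was at 825 ± 77.6 in bone and 1.14 ± 0.269 in thymus, and S100a9 at 848 ± 152 and 2.08 ± 0.453. B cell markers were higher in bone for 9 of 10, and 10 adjusted over the list alone (camera adjusted p = 4.52e-06, adjusted p = 0.0839 with an estimated correlation), and Igll1 of B cell precursors was at least 1100-fold higher there. Erythroid markers were higher in bone for 3 of 6, also 3 adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.236 with an estimated correlation), and 2 of those calls, Hbb-b1 and Alas2, were lost when any 1 bone library was left out. The erythroid list was also lost with RLE factors (adjusted p = 0.056) and without thymus 1-3 (adjusted p = 0.0682). In thymus, 9 of 15 thymocyte markers were above bone, and 12 adjusted over the list alone (camera adjusted p = 0.0057, adjusted p = 0.402 with an estimated correlation). Lck, a T cell kinase gene, was at 14.5 ± 6.31 in thymus and 2.86 ± 0.416 in bone (2.34 ± 0.48). Thymic epithelial markers were higher in thymus for 3 of 11, and 4 adjusted over the list alone (camera adjusted p = 0.0311, adjusted p = 0.285 with an estimated correlation), and the call of Aire was lost when any 1 thymus library was left out. Keratinocyte markers were higher for 5 of 13, also 5 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.433 with an estimated correlation), with Krt5, on both lists, at 2.44 ± 0.807 in thymus and 0.08 ± 0.0232 in bone. Pericyte and smooth muscle markers had 7 higher and 3 lower of 15, the same adjusted over the list alone (camera adjusted p = 0.00709, adjusted p = 0.128 with an estimated correlation). Des, encoding desmin, was at 691 ± 140.1 in thymus and 12.6 ± 4.3 in bone (5.78 ± 0.30), and Cspg4, encoding the NG2 proteoglycan, was lower (-3.16 ± 0.20). The antibody targets were lower in thymus for 4 and higher for 1 of 8, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0401, adjusted p = 0.402 with an estimated correlation). Endothelial markers, Schwann cell and melanocyte markers, and skeletal muscle markers did not pass (adjusted p = 0.469, 0.205 and 0.985).

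Thymus was compared with skin to describe how its mesenchymal cells differ from those of the dermis. The thymus cells carried Mmp9, a gelatinase gene, at 549 ± 76.4 CPM against 0.674 ± 0.273 (9.65 ± 0.30, adjusted p = 4.79e-09), and Des at 691 ± 140.1 against 11.7 ± 2.31 (5.89 ± 0.30). Col6a4 was higher in thymus (8.39 ± 0.42), as was Colq, encoding the collagen tail of acetylcholinesterase (8.39 ± 0.44). Atcay had 0 reads in skin and was at least 2510-fold higher in thymus. Skin cells carried Hoxc8 at 33.6 ± 0.793, and it was lower in thymus by 3810-fold (95% counting interval 1300 to 18500). Zic1, a zinc finger transcription factor gene, was at 24.9 ± 4.36 in skin and lower in thymus by 4280-fold (95% counting interval 1180 to 35400). Krt71, a keratin of the inner root sheath of hair follicles, was at 129 ± 96.5 in skin (73.4 without skin 3), and 3 reads fell on it in the thymus libraries. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 3013 genes were higher and 2865 lower in thymus, 1914 and 1534 by at least 2-fold. With library size only the split became 7219 higher and 1239 lower, with the median of all genes moved by 0.63 on the log2 scale, and on log2 of RPKM plus 1 it was 6482 and 1182. The collagens Col1a1, Col1a2 and Col3a1 took 24.4 ± 0.772% of the gene reads in skin, 4.45 ± 0.365% in thymus and 6.64 ± 0.337% in bone. Whether these collagens account for the whole shift was not tested. Directions against skin are relative to the bulk of genes. In mm10, Mmp9 lies on chromosome 2, 164948251 to 164955846, Des on chromosome 1, 75360344 to 75367715 and Zic1 on chromosome 9, 91360345 to 91365799.

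Pericyte and smooth muscle markers were higher in thymus than in skin for 11 of 15, or 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.98e-07, adjusted p = 0.0305 with an estimated correlation). Notch3, a receptor gene of mural cells, was at 254 ± 48.2 in thymus and 10.5 ± 2.64 in skin (4.59 ± 0.27). Rgs5, a pericyte signalling regulator, was at 15.3 ± 4.53 and 0.674 ± 0.324 (4.49 ± 0.34). Thymopoietic ligands were higher for 10 and lower for 2 of 15, the same adjusted over the list alone (camera adjusted p = 0.00191, adjusted p = 0.174 with an estimated correlation). Ccl19 and Flt3l were higher in thymus (3.71 ± 0.19 and 2.85 ± 0.25), and Fgf7, a growth factor gene for epithelial cells, was lower (-2.03 ± 0.21). MHC class I genes were higher for 10 of 18, and 11 adjusted over the list alone (camera adjusted p = 0.00681, adjusted p = 0.416 with an estimated correlation), including Erap1, a peptide-trimming enzyme gene, and H2-K1 (1.65 ± 0.17 and 1.15 ± 0.20). Pharyngeal and neural crest factors were higher for 9 and lower for 5 of 21, the same adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.402 with an estimated correlation), with Meox1 and Hand2 higher (4.44 ± 0.21 and 3.44 ± 0.27). Thymocyte markers moved with these groups, with 14 of 15 higher in thymus and 15 adjusted over the list alone (camera adjusted p = 2.1e-08, adjusted p = 0.154 with an estimated correlation). Rag1, of the antigen receptor recombinase, was at 35.5 ± 20.3 in thymus and 0.0487 ± 0.0844 in skin. B cell markers had 6 higher and 1 lower of 10, or 7 and 1 adjusted over the list alone, and did not pass (adjusted p = 0.164). Myeloid, erythroid, thymic epithelial and endothelial markers did not pass either (adjusted p = 0.209, 0.457, 0.454 and 0.881).

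Posterior Hox genes were higher in skin than in thymus. Groups 9 to 13 were lower in thymus for 9 of 13, and 10 adjusted over the list alone (camera adjusted p = 2.02e-10, adjusted p = 0.0105 with an estimated correlation). Groups 5 to 8 were lower for 7 of 11, or 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000207, adjusted p = 0.236 with an estimated correlation). Hoxc6 was at 34.2 ± 1.71 in skin and 1.12 ± 0.239 in thymus (-4.93 ± 0.26), and Hoxc10 at 30.1 ± 2.65 in skin, lower in thymus by 5160-fold (95% counting interval 1430 to 42600). Groups 1 to 4 had 6 higher and 1 lower of 10, the same adjusted over the list alone, and did not pass (adjusted p = 0.0638). Dermal fibroblast genes were lower in thymus for 6 and higher for 1 of 11, the same adjusted over the list alone (camera adjusted p = 1.42e-05, adjusted p = 0.182 with an estimated correlation). Twist2, a dermal transcription factor gene, was at 56.9 ± 7.34 in skin and 5.95 ± 0.502 in thymus (-3.26 ± 0.17), and En1 and Tbx15 were lower in thymus (-7.32 ± 0.67 and -4.99 ± 0.17). Collagen and fibre genes were lower for 19 and higher for 5 of 29, or 19 and 7 adjusted over the list alone (camera adjusted p = 6.45e-08, adjusted p = 0.236 with an estimated correlation). Col1a1, of the main fibrillar collagen of skin and bone, was at 97250 ± 7920 in skin and 6963 ± 706 in thymus (-3.80 ± 0.17), and Col3a1 was lower in thymus (-2.72 ± 0.15).

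Stress and inflammatory genes were lower in thymus than in skin as well. Immediate early and dissociation stress genes were lower for 17 of 18, also 17 adjusted over the list alone (camera adjusted p = 3.68e-18, adjusted p = 0.0802 with an estimated correlation), including Myc, Nr4a1 and Dusp1 (-3.05 ± 0.17, -3.43 ± 0.23 and -1.97 ± 0.14). Inflammatory genes were lower for 7 and higher for 2 of 17, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.547 with an estimated correlation). Ccl2, encoding a monocyte chemokine, was at 921 ± 314 in skin and 36.3 ± 6.38 in thymus (-4.67 ± 0.48). Wnt ligands and modulators were lower for 9 and higher for 3 of 22, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.449 with an estimated correlation), but on log2 of RPKM plus 1 they divided 8 to 8. Wnt2 was at 141 ± 24.3 in skin and 9.86 ± 2.86 in thymus (-3.84 ± 0.29), while Axin2, a target of Wnt signalling, was higher in thymus (2.95 ± 0.25). Mesenchymal identity genes were lower for 9 and higher for 4 of 16, the same adjusted over the list alone (camera adjusted p = 0.00038, adjusted p = 0.0572 with an estimated correlation), but 7 were higher and 5 lower with library size only and on log2 of RPKM plus 1. Osteogenic, cell cycle, proteoglycan and retinoic acid genes did not pass (adjusted p = 0.673, 0.266, 0.805 and 0.423), and with library size only more of their members were higher than lower. Chondrogenic, niche, interferon and limb field genes did not pass either (adjusted p = 0.69, 0.447, 0.457 and 0.205), nor did MHC class II genes (adjusted p = 0.457).

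Markers of other skin cells moved with these groups. Keratinocyte markers were lower in thymus for 9 of 13, or 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00779, adjusted p = 0.424 with an estimated correlation), with Krt5 at 14.4 ± 8.06 in skin (-2.56 ± 0.45). Schwann cell and melanocyte markers were lower for 9 and higher for 1 of 12, the same adjusted over the list alone (camera adjusted p = 0.0144, adjusted p = 0.259 with an estimated correlation). Mbp, of myelin, was lower in thymus (-2.62 ± 0.31) and Ngfr, encoding a neurotrophin receptor, higher (2.67 ± 0.38). Skeletal muscle markers were lower for 6 of 8, and 7 adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.285 with an estimated correlation), with Acta1, of skeletal muscle actin, at 11.3 ± 6.12 in skin and 0.181 ± 0.189 in thymus (-5.93 ± 1.30).

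**Figure D2:**
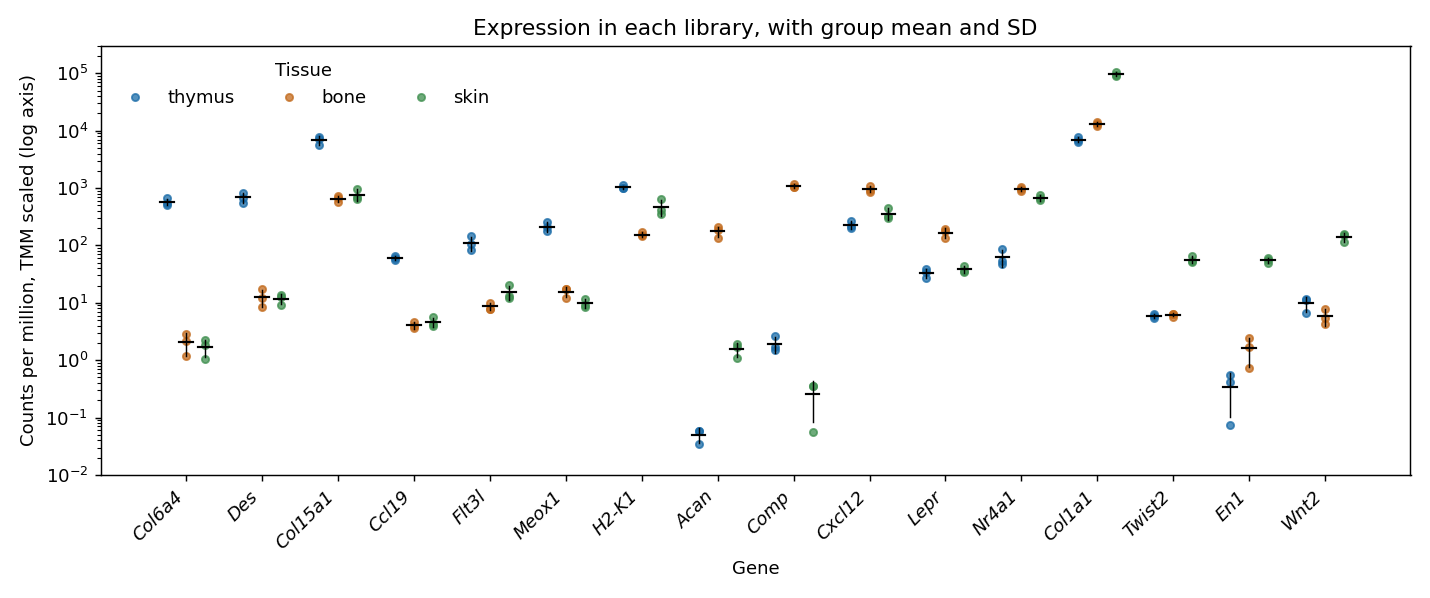
Normalised read counts in CPM (log axis) of 16 genes in each library, with the group mean as a horizontal bar and the SD as a vertical line, n = 3 per tissue. Col6a4, Des and Col15a1 had means of 576, 691 and 6841 in thymus, Acan and Comp 175 and 1102 in bone, and Twist2 and Wnt2 56.9 and 141 in skin, each above the other tissues.

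Bone was compared with skin to describe how mesenchymal cells of the skeleton differ from those of the dermis. The bone cells carried Prg4 at 38500 ± 9156 CPM against 23.7 ± 13.8 in skin (10.67 ± 0.58, adjusted p = 6.16e-07), and Comp at 1102 ± 84.6 against 0.255 ± 0.172 (12.10 ± 0.53). Ibsp had 0 reads in skin, stood at 147 ± 119 in bone and was at least 12000-fold higher there, and without bone 2 its mean fell to 79.1 and the bound with it by 1.86 times. Genes of blood cells were also far higher in bone: Prg2, of an eosinophil granule protein, was at least 8890-fold higher and Elane, of neutrophil elastase, at least 3890-fold. Skin cells carried Akr1c18, a hydroxysteroid dehydrogenase gene, at 730.1 ± 52.4 against 0.422 ± 0.491 (-10.71 ± 0.88, adjusted p = 1.02e-05). Zic1 was at least 2600-fold lower in bone, and the hair follicle keratin gene Krt71 was lower by 20800-fold (95% counting interval 5750 to 172000), where the skin mean fell by 1.76 times without skin 3. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 3702 genes higher and 3661 lower in bone, 2559 and 1885 by at least 2-fold. With library size only these were 7474 and 1391, with the median of all genes moved by 0.69 on the log2 scale, and on log2 of RPKM plus 1 they were 6226 and 1542.

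Cartilage and bone genes were higher in bone than in skin. Chondrogenic genes were higher for 16 of 17, also 16 adjusted over the list alone (camera adjusted p = 3.68e-18, adjusted p = 0.0105 with an estimated correlation), with Acan and Hapln1, encoding a hyaluronan link protein, among them (6.81 ± 0.27 and 8.38 ± 0.47). Osteogenic genes were higher for 11 and lower for 2 of 15, or 11 and 3 adjusted over the list alone (camera adjusted p = 6.21e-05, adjusted p = 0.0572 with an estimated correlation). Runx2, a transcription factor gene needed for osteoblasts, was at 46.6 ± 16.9 in bone and 2.92 ± 0.705 in skin (4.00 ± 0.30), and Spp1 was higher (10.97 ± 0.84). Haematopoietic niche factors were higher for 8 and lower for 3 of 12, the same adjusted over the list alone (camera adjusted p = 0.00736, adjusted p = 0.236 with an estimated correlation). Foxc1 was at 85.2 ± 5.53 in bone and 2.67 ± 0.0841 in skin, Lepr was higher in bone (2.14 ± 0.19) and Csf1, a macrophage growth factor gene, lower (-1.62 ± 0.18). Proteoglycans were higher for 6 and lower for 2 of 12, the same adjusted over the list alone (camera adjusted p = 0.0311, adjusted p = 0.416 with an estimated correlation), with Fmod at 819 ± 239 in bone and 35.1 ± 11.8 in skin. Pericyte and smooth muscle markers were higher for 7 and lower for 2 of 15, the same adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.179 with an estimated correlation), with Cspg4 higher (3.84 ± 0.21) and Kcnj8 lower (-4.02 ± 0.27). Blood markers moved with these genes, as 12 of 16 myeloid markers were higher in bone, also 12 adjusted over the list alone (camera adjusted p = 3.55e-20, adjusted p = 0.07 with an estimated correlation). B cell markers were higher for 10 of 10, also 10 adjusted over the list alone (camera adjusted p = 2.74e-06, adjusted p = 0.146 with an estimated correlation), and thymocyte markers for 10 of 15, or 11 adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.25 with an estimated correlation). Of the thymocyte markers, Rag1, Dntt and Lck were at 21 to 32.2, 9.74 to 34.7 and 2.4 to 3.21 CPM across the bone libraries. Themis was at 0 in bone and Cd8b1 at most at 0.315, so the name of the list does not tell which cells gave these reads.

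Hox groups differed between bone and skin in both directions. Groups 9 to 13 were higher in bone for 7 and lower for 2 of 13, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.182 with an estimated correlation), with Hoxa11 higher and Hoxc9 lower (7.62 ± 0.34 and -3.09 ± 0.41). Groups 5 to 8 were lower for 4 and higher for 1 of 11, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.416 with an estimated correlation), with Hoxc8 at 1.85 ± 0.943 in bone against 33.6 ± 0.793 in skin (-4.18 ± 0.40). Of groups 1 to 4, 4 of 10 genes were lower in bone, also 4 adjusted over the list alone, against 3 higher and 3 lower with library size only, and the list did not pass (adjusted p = 0.102). Hoxb2 and Hoxb3 were lower in bone (-4.50 ± 0.29 and -2.39 ± 0.32). Pharyngeal and neural crest factors and limb field factors did not pass (adjusted p = 0.0501 and 0.406), with Eya2 and Tbx4 higher in bone (4.00 ± 0.37 and 8.71 ± 0.61).

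Collagens and dermal genes were lower in bone than in skin. Collagen and fibre genes were lower for 22 and higher for 4 of 29, the same adjusted over the list alone (camera adjusted p = 1.42e-11, adjusted p = 0.179 with an estimated correlation), with Col1a1 and Col1a2 lower (-2.89 ± 0.17 and -2.45 ± 0.16). Dermal fibroblast genes were lower for 7 of 11, also 7 adjusted over the list alone (camera adjusted p = 0.000582, adjusted p = 0.236 with an estimated correlation). Twist2 was lower in bone (-3.20 ± 0.17) and Dpp4, a surface peptidase gene, was at 55 ± 13.6 in bone and 789 ± 46.9 in skin (-3.84 ± 0.32), while Tbx15 was at 144 ± 8.89 and 139 ± 20.3. Interferon response genes were lower for 17 of 20, also 17 adjusted over the list alone (camera adjusted p = 0.000468, adjusted p = 0.574 with an estimated correlation), with Irf1 lower (-1.50 ± 0.18). MHC class I genes were lower for 14 and higher for 1 of 18, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.449 with an estimated correlation). Inflammatory genes were lower for 8 and higher for 2 of 17, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.547 with an estimated correlation), with Ccl11 lower (-4.46 ± 0.30). Immediate early and stress genes were lower for 10 and higher for 2 of 18, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.426 with an estimated correlation). Hspa1a, a heat shock gene that may share reads with its near-identical copy Hspa1b, was lower in bone (-3.95 ± 0.42). Mesenchymal identity genes were lower for 8 and higher for 1 of 16, the same adjusted over the list alone (camera adjusted p = 0.000322, adjusted p = 0.0572 with an estimated correlation), but 7 were higher and 5 lower with library size only, and 7 and 6 on log2 of RPKM plus 1. Skin cell markers moved with them, as keratinocyte markers were lower in bone for 12 of 13, and 13 adjusted over the list alone (camera adjusted p = 1.94e-05, adjusted p = 0.25 with an estimated correlation), with Krt5 and Krt17 lower (-7.47 ± 0.58 and -8.92 ± 0.74). Without skin 3 the skin means of Krt17, Perp, Trp63 and Cldn4 fell by 1.66, 2.15, 1.56 and 2.85 times. Skeletal muscle markers were lower for 8 of 8, also 8 adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.315 with an estimated correlation). Schwann cell and melanocyte, erythroid, endothelial, thymic epithelial, cell cycle and MHC class II genes and thymopoietic ligands did not pass (adjusted p = 0.266, 0.233, 0.69, 0.387, 0.136, 0.138 and 0.875).

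Of 102 tests over 34 lists, 56 passed with the preset correlation and 7 with an estimated correlation. The 7 were myeloid, osteogenic, chondrogenic and Hox 9 to 13 genes between thymus and bone, pericyte and Hox 9 to 13 genes between thymus and skin, and chondrogenic genes between bone and skin. The median, mean and test of a list differed in sign in 9 results, none of which passed. The median was above 0, with the mean below, for mesenchymal identity between thymus and bone, endothelial markers between bone and skin, and proteoglycans and BMP and TGF-beta genes between thymus and skin. It was below 0, with the mean above, for pharyngeal factors between thymus and bone, myeloid markers and niche factors between thymus and skin, and adipogenic genes and thymopoietic ligands between bone and skin.

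**Figure D3:**
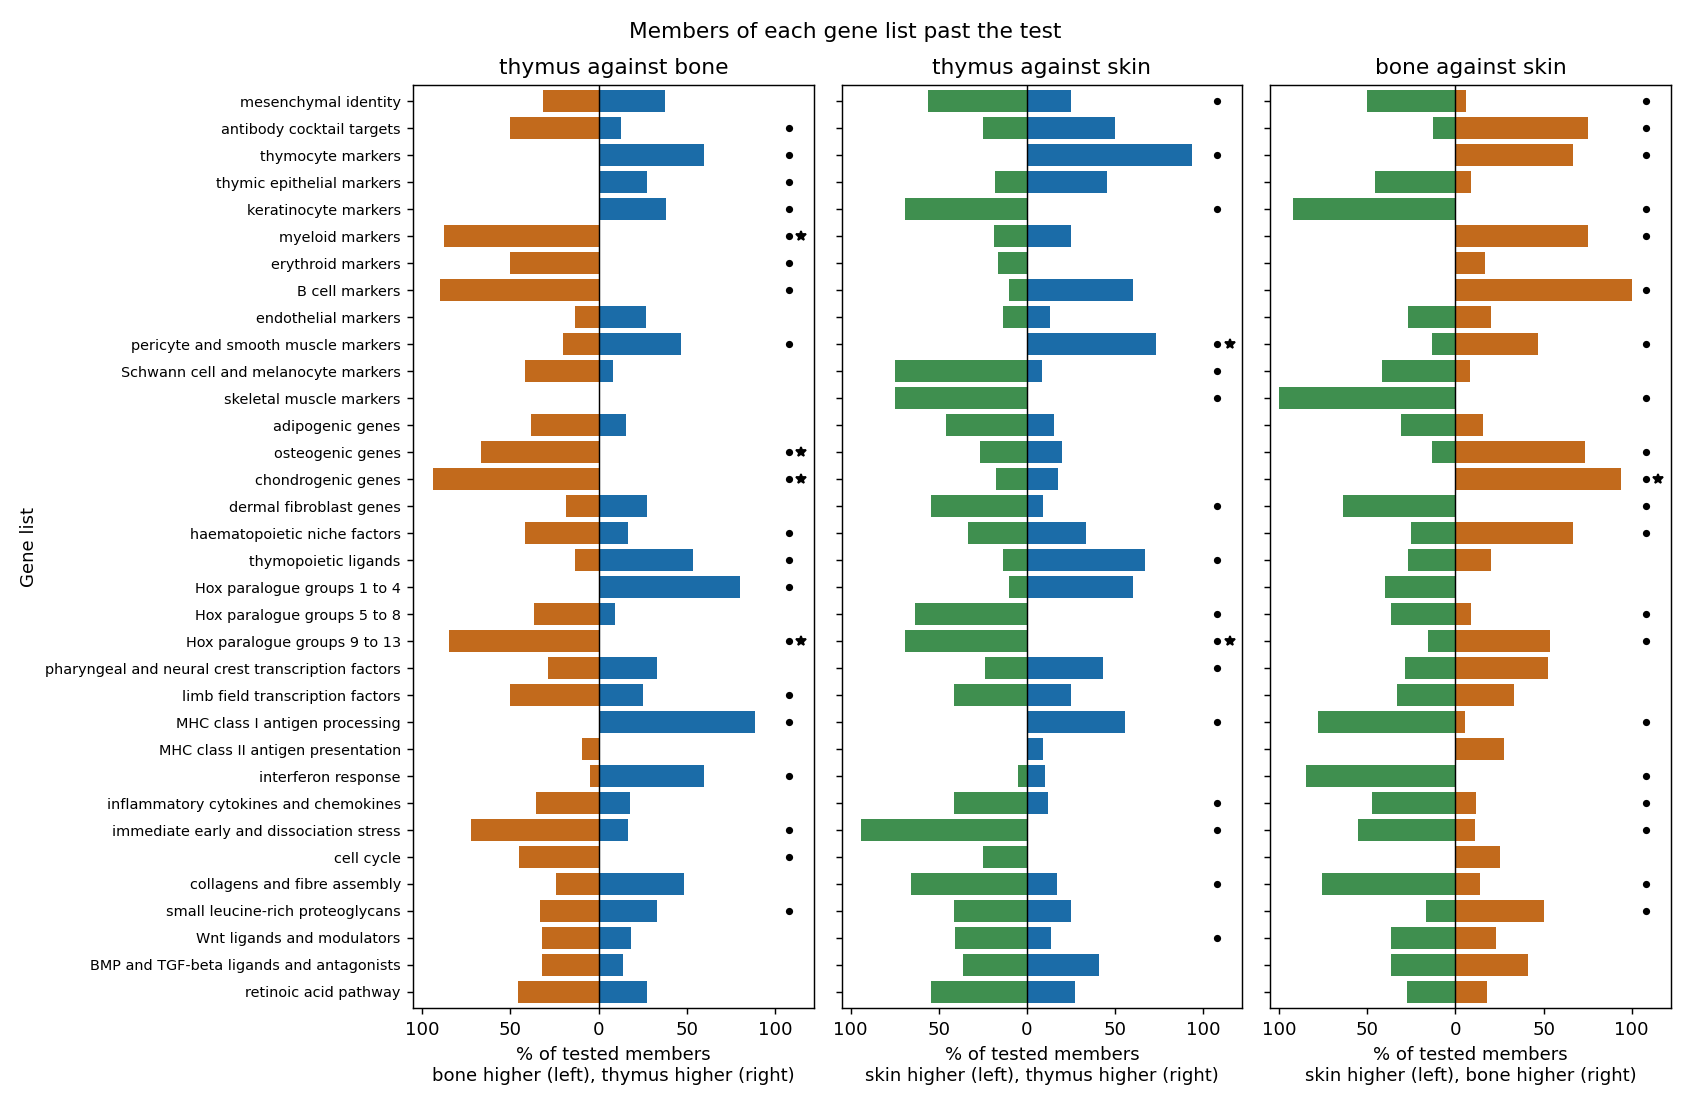
Percent of the tested members of each of 34 gene lists (rows) called higher or lower in each comparison (panels) by edgeR's quasi-likelihood test over all genes. A dot marks a camera adjusted p under 0.05 with the preset correlation and a star 1 of the 7 calls that also held with an estimated correlation, and the majority for mesenchymal identity against skin, and for 9 list results against skin that did not pass, turned with library size only.

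Genes that set 1 tissue apart were taken as those changed by at least 2-fold in the same direction against both other tissues. Thymus stood apart in Hsd11b1, encoding the enzyme that regenerates active glucocorticoid, at 444 ± 147 CPM against 6.69 ± 3.17 in bone and 6.26 ± 3.96 in skin, or 4.11 without skin 3 (6.06 ± 0.60 and 6.15 ± 0.61). Synpo2, an actin-binding protein gene of muscle, was at 136 ± 26.9 in thymus (5.89 ± 0.43 and 6.12 ± 0.44), Kcng4, a potassium channel subunit gene, at 70 ± 9.83 and Pcdh12, a protocadherin gene, at 61.3 ± 9.7. Rspo2, an enhancer of Wnt signalling, was low in thymus, at 0.0233 ± 0.017 against 52.5 ± 9.98 in bone and 8.41 ± 2.96 in skin. Bone stood apart in Mmp13, a collagenase gene, at 629 ± 452 (374 without bone 2), and Mpo, the neutrophil peroxidase gene, at 184 ± 45.7. Bmp7 was low in bone, at 0.392 ± 0.325 against 20.1 ± 8.67 in thymus and 119 ± 30.4 in skin. Skin stood apart in Irx1, an Iroquois homeobox gene, at 75.3 ± 19.9 against 1.01 ± 0.78 in thymus, or 0.665 without thymus 1-3, and 0.0773 ± 0.0883 in bone. Low in skin were Spib, a lymphoid and dendritic cell factor gene, at 0.24 ± 0.0524 (7.15 ± 0.22 in thymus minus skin and 7.29 ± 0.22 in bone minus skin), and Tspan15, a tetraspanin gene, at 0.583 ± 0.373 (7.10 ± 0.48 and 7.65 ± 0.49).

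By these limits thymus had 633 genes higher and 599 lower than in both other tissues, bone 1018 and 603, and skin 782 and 1180. The higher genes of bone include the neutrophil genes Elane and Mpo, so RNA of other cells may contribute to that count. Those of skin include the hair follicle gene Krt71 and the keratin genes Krt27, Krt73, Krt35, Krt28 and Krt25. Their skin means fell by 1.54 to 2.96 times without skin 3. The lower genes of skin include Rag1 and the eosinophil gene Prg2. RNA of other cells may thus contribute to both skin counts as well. Independent lists of the same lengths would share 169 and 169 genes for thymus, 282 and 167 for bone, and 185 and 313 for skin. Simulated unchanged groups gave means of 0 higher, and of 0 to 0.05 lower, over 20 draws per tissue. Where no gene is changed, almost none passes in either comparison, so an overlap near 0 follows by construction. These draws therefore give no baseline for the overlap of real comparisons that share a tissue. Both comparisons of a tissue share its 3 libraries, which are too few to be divided. Part of the excess over independent lists may thus come from the shared libraries. On log2 of RPKM plus 1 the genes lower than in both others numbered 231 for thymus and 207 for bone, and in skin 295 were higher and 1072 lower. With library size only, 353 were higher and 2922 lower in skin.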

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

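The fits without the genes on chromosomes X and Y were chosen only after the result was seen; they gave 2496 higher and 2443 lower genes between thymus and bone, 2902 and 2775 between thymus and skin, and 3556 and 3525 between bone and skin. With library size only, genes higher and lower in thymus than in skin numbered 7219 and 1239, and in bone than in skin 7474 and 1391. On RPKM plus 1, plus 0.1 and plus 1 without a filter they were 6482 and 1182, 6557 and 1196, and 6535 and 1351 for thymus and skin, and 6226 and 1542, 6234 and 1541, and 6689 and 1689 for bone and skin. By construction these settings use no TMM factor, and that factor was lowest in skin. Genes lower than in both other tissues on these RPKM settings were 231, 371 and 223 for thymus and 207, 325 and 193 for bone, with 342 for bone with library size only. Genes higher in skin than in both others were 295, 335 and 311 on RPKM and 353 with library size only, and those lower were 2922 with library size only, 2186 on RPKM plus 0.1, and 1072 and 1063 on RPKM plus 1 with and without the filter. The counts of lower genes thus depended on the number added to RPKM as well as on the scaling. With the replicate number as a block and thymus 1-3 as a level of its own, 1663 genes were higher in thymus than in bone, 1618 of them shared with the 2584 of the unblocked fit, and with 1-3 taken as number 1 there were 2311. Deviations of same-numbered libraries correlated at -0.118 to 0.107 across genes, so the numbers give no sign of pairing. Leaving out each library gave 1977 to 2199 higher and 2008 to 2199 lower genes for thymus and bone, 2333 to 2873 and 2249 to 2842 for thymus and skin, and 2985 to 3519 and 3018 to 3367 for bone and skin. Against both others the ranges were 517 to 645 and 523 to 580 for thymus, 846 to 1035 and 464 to 610 for bone, and 684 to 820 and 1003 to 1248 for skin. Of 102 list tests, 56 passed, 7 with an estimated correlation, 55 with RLE factors, 47 with the block and 55 without thymus 1-3. The cause of the fall under the estimate was not tested. With thymus 1-3 as its own level, the block lost mesenchymal identity, pharyngeal and Wnt genes between thymus and skin, and antibody targets between thymus and bone. Also lost were pericyte, niche and proteoglycan genes in both comparisons with bone, and Hox 9 to 13 genes between bone and skin. MHC class II genes between bone and skin and BMP and TGF-beta genes between thymus and bone passed only with the block. Over 358 results for 204 named genes, 6306 of 6410 values kept their direction and side of the threshold, 104 lost the call and 0 reversed, and the block lost 14. All 358 had passed the threshold, and most were picked from these same data for a large fold or a small p. Such picking favours stability, so these numbers do not describe the called genes at large. Depth limits the folds of genes with few reads in a tissue, which are bounds at 0 reads and carry a counting interval at 1 to 3.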

Other observations

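Among the tests of this part, the one on X- and Y-linked genes was chosen only after the result was seen. Retinoic acid genes did not pass as a list in any comparison (adjusted p = 0.0831, 0.423 and 0.457 between thymus and bone, thymus and skin, and bone and skin), and against skin their majority turned with library size only. Among them Crabp2, a retinoic acid binding protein gene, was at 43.8 ± 11.9 in bone, 0.348 ± 0.105 in thymus and 0.789 ± 0.174 in skin. Aldh1a2, encoding an enzyme that makes retinoic acid, was at 64.8 ± 11.7, 20.1 ± 6.53 and 1.47 ± 0.415 in the same order, while Aldh1a1 was at 8.15 ± 1.99, 40.2 ± 4.66 and 84.8 ± 18. BMP and TGF-beta genes did not pass either (adjusted p = 0.215, 0.819 and 0.579). Chrdl1, a BMP antagonist gene, was at 466 ± 40 in skin, 53.6 ± 3.02 in bone and 16.9 ± 4.77 in thymus, and Ltbp1, which binds latent TGF-beta, at 1402 ± 99.4 in thymus, 232 ± 40.1 in bone and 305 ± 34 in skin. Outside the comparison of thymus and skin described above, Wnt genes did not pass between thymus and bone or between bone and skin (adjusted p = 0.188 and 0.387), and in the latter their majority turned with library size only and on log2 of RPKM plus 1. Adipogenic genes did not pass (adjusted p = 0.813, 0.364 and 0.457), and between bone and skin their majority turned with library size only. Apoe was at 787 ± 41.4 in thymus, 102 ± 19.4 in bone and 162 ± 50.9 in skin, and Lpl, encoding lipoprotein lipase, at 1203 ± 77, 271 ± 62 and 455 ± 64.7.

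Xist had means of 510.4 ± 28.2 CPM in thymus, 525.9 ± 139.4 in bone and 142.6 ± 56.2 in skin, and 4 Y-linked genes summed to 58.4 ± 12.1, 93.9 ± 33.8 and 20.3 ± 3.4 (SD, n = 3). Each library held both, the lowest value being 16.4, so each library may pool cells of both sexes, and both were lower in skin.

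Transcripts of cells that the lineage antibodies should remove stood in each tissue, and RNA from residual cells is a candidate explanation. In bone all 14 pan-leukocyte genes tested, from a list that shares no gene with the myeloid and B cell markers, were higher than in skin with a median log2 fold change of 5, beside Ngp at 825 and S100a9 at 848 CPM, and 10 of the 14 were at 1 or more in skin as well. This is what RNA from residual leukocytes in the bone sort would give, although the gate excluded cells with CD45, CD11b, GR-1 or B220. The same pan-leukocyte genes, all but Arhgdib and Cd53, were also called higher in thymus than in skin, with lower means than in bone. Coro1a was at 14 CPM in thymus, 71.4 in bone and 1.5 in skin. That comparison was not among the tests set beforehand, and leukocyte RNA in the thymus libraries stays open too. In thymus 11 of 14 other T lineage genes were higher than in skin, with Bcl11b, Tox and Gata3 not called and 4 of the 14 at 1 or more in skin, and in skin 7 of 13 other epidermal genes were higher than in bone and 2, Itgb4 and Ppl, lower, with 5 at 1 or more in bone, both under the share set beforehand. Residual thymocytes and residual keratinocytes therefore stay open, as does expression of these genes in the mesenchymal cells of each tissue, which was not tested. Krt71, the hair follicle keratin gene at 129 CPM in skin, is not among the 13 epidermal genes. RNA of hair follicle cells as such was not tested.

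Of 18 immediate early and stress genes, 13 were lower and 3 higher in thymus than in bone, and 17 were lower than in skin (adjusted p = 0.188 and 0.0802 with an estimated correlation, so both list calls are lost there). Stress during dissociation that differed between the tissues may account for part of it. The test used 11 heat shock genes outside that list, whose median log2 fold change was -0.72 between thymus and bone, with 7 lower, and -1.83 between thymus and skin, with 11 lower. Both signs are those that such stress would give, but Hspa1a went the other way between thymus and bone (1.36 ± 0.38). Thymus and bone were prepared differently and the preparation of skin is not given in the sources used here, so stress during the preparation and a difference between the living tissues cannot be separated by these libraries.

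Skin libraries held fewer genes with 1 CPM or more than bone libraries, by 1373.3 on average. Collagen reads that take up the skin libraries could lower that number, and with the composition-corrected scale the gap was 779 genes, against a larger group SD of 179.6. The collagen reads thus are not the whole cause. RNA of other cells in bone and a difference between the tissues remain open.

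For each pair of tissues the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 5101 genes between thymus and bone, 5878 between thymus and skin and 7363 between bone and skin, each the 1 split with as many, and the highest other split called 1, 0 and 0. For 1 tissue against both others, 98 splits of the 9 libraries were used. A result as large came from 3 of them for thymus (1232 genes), 1 for bone (1621) and 1 for skin (1962), with 1555 as the highest other. These shares were under 0.05, but the draws left out the real splits of the other tissues, which can reach such counts. The 3 other splits that kept 1 tissue whole gave 599 to 1555 genes. The remaining 94, whose tested group mixed tissues, gave 0. The outcome thus followed the structure of the samples by tissue, and the shares cannot exclude a random split as the source.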
